A study of Homo sapiens with 8 samples.

How the data were processed

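RNA of WM983B and SK-Mel5 melanoma cells, transduced with pLKO1 lentivirus carrying shp300 or scrambled shRNA, was measured on 8 Affymetrix Human Gene 2.0 ST arrays, 2 per group. Per the labels, puromycin selection at 1.5 µg/mL began 48 h after transduction, RNA was extracted with Qiagen RNeasy Plus, and it was labelled with the WT Plus kit. The deposited values are log2 expression values per gene feature, which the authors made by RMA (background correction, quantile normalization and median polish) with affy 1.36.1 in R 2.15.1. The mapping of probes to genes is not given in the sources used here. The 4 arrays of each line share a distribution that differs from the other line's, so the lines were apparently normalized separately. Each feature ID is an Entrez Gene number with a suffix. Of 23786 features, 22458 matched 1 symbol, 0 matched several and 1328 matched none. Every deposited column was used (0 left out), and no feature was filtered.

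Groups were taken from the labels. limma 3.58.1 in R 4.3.3 fitted all 8 arrays in a model of 4 groups (lmFit and eBayes, default settings). Contrasts were shp300 minus scrambled in each line, the difference of these 2 changes (WM983B minus SK-Mel5), and scrambled WM983B minus scrambled SK-Mel5. An additive model of line and shRNA gave the change over both lines. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over all features within each of the 5 comparisons, and features with an adjusted p under 0.05 were called. "Rose" and "fell" refer to called features. A called feature is not thereby a separate gene, and changes are on the log2 scale unless a fold is given.

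Gene lists for 23 pathways and states and 5 other cell types were fixed before the data were examined, as were the tests, the named genes and the alternative settings. The mitochondrially encoded list had no measured member, which left 27 lists. Some lists share genes, so their results are not independent of each other. For example, FOS, EGR1, IER3 and MYC are in both the ERK output and the immediate early list. JUN and CCN1 are in both the dedifferentiated and the immediate early list. FOSL1 is in the ERK and dedifferentiated lists, and CXCL8 in the ERK and inflammatory lists. Each was tested against all other genes by limma's camera with a preset correlation of 0.01 and adjusted over the lists within a comparison. A correlation estimated per list and fry were alternatives. The rule for named genes took EP300, CREBBP, MITF and FOXM1. It added the 10 largest called rises and falls with 1 symbol per comparison (5 for the difference between lines), where the arrays of the groups did not overlap, a condition not applied to the difference. From each list described it took the 4 members with the smallest p, of which the text prints up to 4. Genes named in the other observations were chosen after their values were seen.

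The alternatives were the replicate number as a block, dim features left out (mean below the median feature), centring each array on its median, quantile normalization or cyclic loess of all 8 arrays, eBayes with trend and robust, array weights, an adjusted p under 0.1, a minimum of 1.5-fold, fits of only the arrays compared, the mean of both lines in the 4-group model, and leaving out each array in turn. A lone array left in a group is then assumed to vary like the other groups. The methods were tested on simulated data with the spread of these arrays and 200 changed features. Changes of 1 log2 unit were recovered for 52.2% of features in WM983B, 56.7% in SK-Mel5, 85.1% over both lines and 16.4% in the difference between lines. For changes of 2 the shares were 100%, 97%, 100% and 86.4%. At 0.5 log2 units they were 0%, 1.49%, 34.3% and 0%. False calls were at most 9.26% of the calls in the simulation. Only 200 of 23786 features changed there, whereas limma called 5352 in WM983B. The adjusted p depends on that share, so the simulated recovery does not carry over to the data. Of the WM983B calls, 3650 changed at least 1.5-fold and the rest changed less.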

Results

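RNA levels were measured on 8 Affymetrix Human Gene 2.0 ST arrays from 2 human melanoma cell lines, WM983B and SK-Mel5. Cells of each line carried a lentiviral short hairpin RNA (shRNA) against EP300, the gene of the histone acetyltransferase p300 (shp300), or a scrambled shRNA. The 4 groups held 2 arrays each, and their number limits the precision of every value. Each array gave log2 values for 23786 features, of which 22458 carried 1 gene symbol. Arrays of one group correlated at r = 0.995 and 0.994 in WM983B (scrambled, shp300) and at 0.994 and 0.992 in SK-Mel5. The labels do not say whether the 2 arrays of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. The median of the array values was 4.27 in WM983B and 2.99 in SK-Mel5, a difference of 1.28, while the medians within a line lay within 0.017 and 0.050 of each other. Each line was thus apparently normalized on its own, and levels of the 2 lines are not on a common scale.

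The first question was whether the targeted RNA fell. In SK-Mel5, EP300 RNA fell by 1.01 on the log2 scale (2.02-fold, SE 0.155, n = 2 arrays per group, limma adjusted p = 0.00377), from 7.05 ± 0.203 (SD) to 6.03 ± 0.088. In WM983B it was 7.16 ± 0.084 with scrambled shRNA and 7.09 ± 0.240 on the arrays labelled shp300, a change of -0.07 (95% interval -0.43 to 0.29, adjusted p = 0.832). Because EP300 RNA was not measurably lower there, the WM983B results below are those of arrays labelled shp300. CREBBP, the gene of the closely related acetyltransferase CBP, rose in both lines, by 0.70 in WM983B (SE 0.137, adjusted p = 0.00846) and by 0.92 in SK-Mel5 (adjusted p = 0.00328). Its WM983B call was lost without WM983B scrambled replicate 2 (adjusted p = 0.0573). MITF, the master regulator of the melanocyte lineage, fell by 1.71 in WM983B (3.27-fold, SE 0.143, adjusted p = 0.000173). In SK-Mel5 its change was -0.25 (SE 0.143, adjusted p = 0.31). FOXM1, a transcription factor of G2 and mitosis, fell by 1.93 in WM983B (SE 0.118, adjusted p = 5.71e-05) and by 1.95 in SK-Mel5 (adjusted p = 8.27e-05). The study followed FOXM1 as a p300 effector chosen with these arrays, so its fall here is not independent evidence. The Entrez Gene numbers of their features were 2033 for EP300, 1387 for CREBBP, 4286 for MITF and 2305 for FOXM1.

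**Figure D1:**
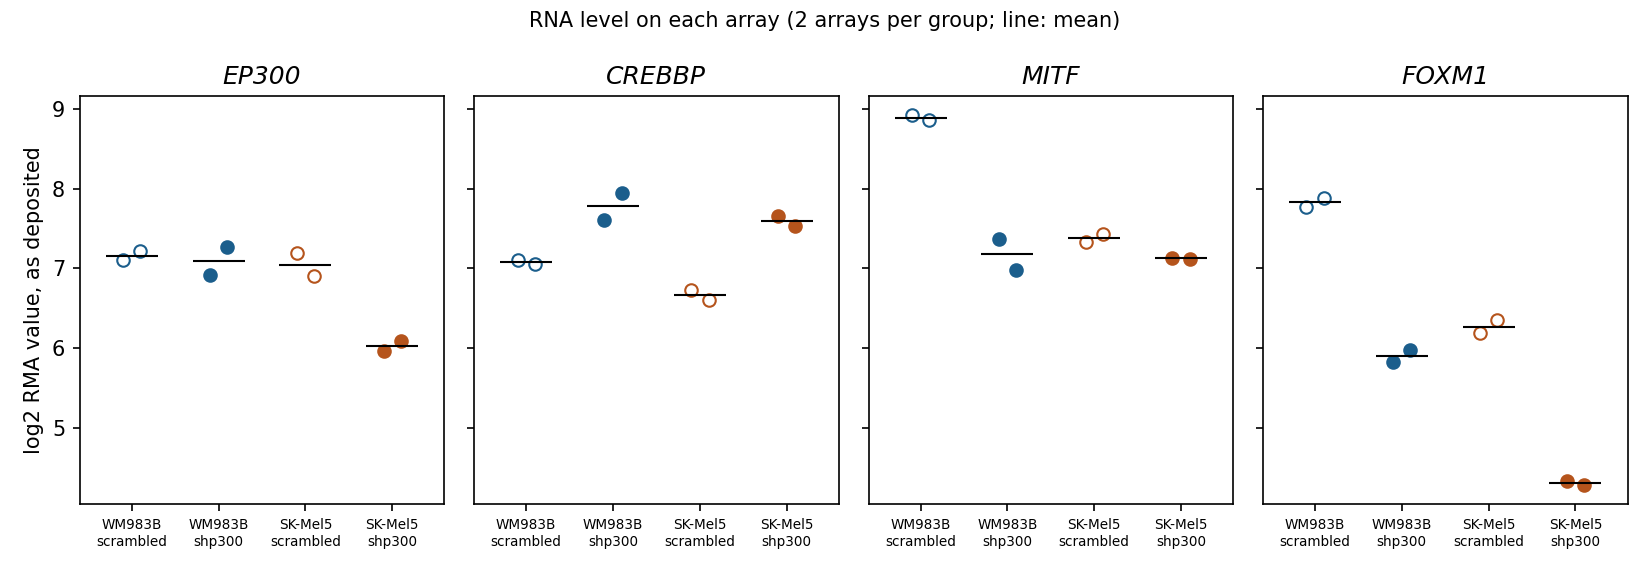
Deposited log2 values of EP300, CREBBP, MITF and FOXM1 on each of the 8 arrays, with a line at the mean of each group of 2. FOXM1 lies lower with shp300 in both lines, EP300 only on the SK-Mel5 arrays (6.03 against 7.05), and MITF differs most in WM983B (7.18 against 8.89); values of the 2 lines are not on a common scale.

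In WM983B, the largest rise on the arrays labelled shp300 was in INHBA, a subunit of activin A, at 5.27 (SE 0.252). The cytokine genes IL1B (4.31), CXCL8 (3.68) and LIF (3.47) rose with it, as did STC1 (4.15), LIPH (3.56), MIR100HG (3.55), the protease inhibitor gene TFPI2 (3.52), the CDK inhibitor gene CDKN2B (3.45) and PMEPA1 (3.43). The largest fall was in TYRP1, an enzyme of melanin synthesis, at -4.05 (16.6-fold, SE 0.117). Also among the 10 largest falls were the melanocyte channel gene TRPM1 (-3.85), the melanosome gene MLANA (-3.41), CST1 (-3.69), LINC00589 (-3.65), ATP6V0D2 (-3.44), CDCA7 (-3.13), RPH3A (-3.12), CRYAB (-3.10) and PLA1A (-3.10). By the rule that chose these 20 genes, both arrays of the higher group lay above both of the lower group. The lower group stood below the median feature, and was not shown to be above background, for IL1B (percentile 23.1), INHBA (31), RPH3A (32.2), LIPH (32.3), LINC00589 (38.3), STC1 (42.5), CDCA7 (43.8) and TFPI2 (47.6), so the size and rank of these changes are uncertain. limma called 5352 features, 2597 higher and 2755 lower, of which 1414 changed at least 2-fold. The count was 3268 without WM983B scrambled replicate 1 and 3146 without WM983B scrambled replicate 2.

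Genes of cell division fell together in WM983B. All 26 measured S phase and DNA replication genes fell (all 26 also adjusted over the list alone; median -1.76), among them GINS2 (-2.39), MCM5 (-2.34), MCM6 (-1.99) and TYMS (-1.91). Of 26 G2/M and mitosis genes, 25 fell (25 adjusted over the list alone; median -1.358), among them AURKB (-1.49), KIF20A (-1.48) and PLK1 (-1.39). This list holds FOXM1, which the study chose on these arrays, so its direction is not independent evidence. Of 18 DNA damage repair genes, 16 fell (16 adjusted over the list alone; median -1.42), as EXO1 (-2.39), BLM (-2.00) and FANCI (-1.65) did. The camera test against all other genes gave adjusted p = 1.85e-26, 1.49e-21 and 3.91e-14 for the 3 lists, and adjusted p = 0.056, 0.0654 and 0.0654 with an estimated correlation. Of 12 histone genes, 8 fell and 2 rose (the same numbers adjusted over the list alone), with H4C1 at -2.73, H1-5 at -2.20 and H2BC5 at 2.50 (adjusted p = 0.000514; adjusted p = 0.0675 with an estimated correlation). Of 20 MYC target and ribosome biogenesis genes, 11 fell (11 adjusted over the list alone), among them CDC25A (-1.16), FBL (-0.68) and CAD (-0.68), with adjusted p = 2.2e-05, and adjusted p = 0.0722 with an estimated correlation. Nuclear genes of the respiratory chain fell in 7 of 17 (9 adjusted over the list alone), as UQCRC2 (-0.76) and NDUFA9 (-1.01) did (adjusted p = 0.00175; adjusted p = 0.115 with an estimated correlation).

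The pigment program fell in WM983B while markers of dedifferentiated melanoma rose. Of 21 pigment cell and melanosome genes, 13 fell and none rose (13 adjusted over the list alone; median -0.78), among them TYRP1, TRPM1, MLANA and OCA2 (-2.50). Of 20 other published MITF target genes, 11 fell and 1 rose (13 and 1 adjusted over the list alone), with PPARGC1A at -1.85, BEST1 at -1.70, GMPR at -1.38 and IRF4 at -1.33. Of 18 dedifferentiated or invasive melanoma markers, 13 rose (14 adjusted over the list alone; median 1.28), among them CCN2 (2.70), CCN1 (2.56) and the receptor gene NGFR (2.19). Camera gave adjusted p = 2.27e-09, 5.31e-06 and 1.76e-09 for the 3 lists, and adjusted p = 0.0983, 0.0654 and 0.067 with an estimated correlation.

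Of 20 ERK pathway output genes, 14 rose and 2 fell (the same numbers adjusted over the list alone), with DUSP5 at 2.32, SPRY2 at 1.57 and CCND1 at 1.50 (adjusted p = 7.89e-08; adjusted p = 0.056 with an estimated correlation). Immediate early genes, which also respond to handling, rose in 12 of 16 and fell in 1 (13 and 1 adjusted over the list alone), with EGR3 at 2.48, FOSB at 2.02 and IER2 at 1.33 (adjusted p = 2.27e-09; adjusted p = 0.056 with an estimated correlation). Of 19 inflammatory and NF-kB genes, 12 rose and 1 fell (13 and 1 adjusted over the list alone), among them CCL2 (2.68) and PTGS2 (1.93), with adjusted p = 1.56e-06, and adjusted p = 0.0783 with an estimated correlation. TGF-beta target and matrix genes rose in 10 of 22 (10 adjusted over the list alone), as ITGA5 (2.32), SKIL (1.72), TGFB1 (1.48) and COL4A1 (1.22) did (adjusted p = 0.000129; adjusted p = 0.0654 with an estimated correlation). Interferon response genes rose in 11 of 23 and fell in 1 (11 and 2 adjusted over the list alone), with IRF9 at 1.33, OAS2 at 1.05, RSAD2 at 1.05 and RIGI at 0.99. Their adjusted p was 0.000804, and adjusted p = 0.0654 with an estimated correlation. Of 18 p53 target, CDK inhibitor and senescence genes, 11 rose and 2 fell (11 and 3 adjusted over the list alone), with SESN2 at 1.32, TNFRSF10B at 0.97 and RRM2B at -1.52 (adjusted p = 0.00111; adjusted p = 0.0654 with an estimated correlation).

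Weaker list results in WM983B concerned survival genes and marker genes of other cells. Apoptosis regulators rose in 7 of 19 and fell in 3 (9 and 4 adjusted over the list alone), with the survival genes MCL1 at 1.45 and BCL2 at -1.88 (adjusted p = 0.0454; adjusted p = 0.233 with an estimated correlation). That call was lost without WM983B scrambled replicate 1 (adjusted p = 0.0603), WM983B shp300 replicate 2 (0.0931), SK-Mel5 scrambled replicate 1 (0.0709) or SK-Mel5 scrambled replicate 2 (0.0709). Of 8 markers of HEK293T, a line commonly used to package lentivirus, 2 rose, CDH2 (1.13) and NEFM (0.49), with adjusted p = 0.0146, and adjusted p = 0.0983 with an estimated correlation. The list call was lost without WM983B shp300 replicate 1 (adjusted p = 0.0539). The NEFM call (adjusted p = 0.0433) was lost without WM983B scrambled replicate 1 (0.0546) or 2 (0.239), WM983B shp300 replicate 1 (0.0768) or 2 (0.189), and SK-Mel5 scrambled replicate 1 (0.0667) or 2 (0.0667). It was also lost with the replicate number as a block (0.0913), after quantile normalization (0.0944), with trend and robust eBayes (0.0656) and from the 4 WM983B arrays alone (0.0647). Leaving out dim features ended the calls of the interferon (adjusted p = 0.0954), apoptosis (0.0954), HEK293T (0.0954) and histone lists (0.147), whose medians were then 0.256, 0.377, 0.737 and -0.941, against 0.374, 0.375, 0.267 and -1.171 with all features. Among 12 lysine acetyltransferase genes 3 rose and 2 fell, HAT1 by -1.27 and KAT6A by 0.58, and the list did not pass (adjusted p = 0.879). The KAT6A call was lost without WM983B scrambled replicate 2 (adjusted p = 0.052). The other lists that did not pass had adjusted p = 0.0663 (stress response, 9 of 21 genes higher and 4 lower), 0.462 (lysosome), 0.568 (antigen presentation), 0.758 (cholesterol), 0.758 (hypoxia, with a median of -0.18 and a mean of 0.02), 0.568 (fibroblast), 0.732 (keratinocyte, with a median of -0.10 and a mean of 0.09), 0.758 (leukocyte) and 0.98 (endothelial). The stress response list passed without WM983B scrambled replicate 2 (adjusted p = 0.0496), after quantile normalization (0.0349) and after cyclic loess (0.0365).

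In SK-Mel5, where EP300 RNA fell, the largest rises were in SCG3 (3.19, SE 0.106) and SCG2 (3.18), granins of neuroendocrine vesicles, and in the granin gene CHGB (2.996). The other 7 largest rises were ANXA1 (2.74), the synaptic vesicle gene UNC13A (2.67), the immediate early gene EGR1 (2.41), the dynein gene DYNLRB1 (2.38), smooth muscle actin ACTA2 (2.30), the collagenase gene MMP1 (2.30) and MAPRE3 (2.26). The largest fall was in the thiamine transporter gene SLC19A2, at -3.36 (10.2-fold, SE 0.111). It was followed by PKD1L1-AS1 (-3.27), PRKCH (-3.24), ATP1B1 (-3.16), MAP2K6 (-3.06), DEPDC1 (-2.95), LOC100505912 (-2.94), DEPDC1B (-2.82), SLCO4A1 (-2.76) and the stress granule gene G3BP2 (-2.75). The rule that chose these 20 genes required both arrays of the higher group to lie above both of the lower group. The lower group stood below the median feature, and was not shown to be above background, for SCG3 (percentile 18), DEPDC1B (39), SCG2 (39.7), MMP1 (41.3), MAP2K6 (44.3), DEPDC1 (45), UNC13A (45.4), PRKCH (48.4), CHGB (48.7) and LOC100505912 (49.3), which leaves the size and rank of their changes uncertain. limma called 3894 features, 1801 higher and 2093 lower, of which 956 changed at least 2-fold (283 higher, 673 lower). The count was 2143 without SK-Mel5 scrambled replicate 1, 2279 without SK-Mel5 scrambled replicate 2, and 2050 from the 4 SK-Mel5 arrays alone.

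Cell-division genes fell in SK-Mel5 as well. Of 26 G2/M and mitosis genes, 25 fell (25 adjusted over the list alone; median -1.90), among them BUB1 (-2.62), TOP2A (-2.09), PLK1 (-2.09) and KIF20A (-1.93). FOXM1 belongs to this list and was chosen on these arrays, so the direction is not independent evidence. All 26 S phase genes fell (26 adjusted over the list alone; median -1.35), with GINS1 at -2.08, CCNA2 at -2.03, MCM4 at -1.74 and RRM2 at -1.62. DNA damage repair genes fell in 14 of 18 and rose in 1 (15 and 1 adjusted over the list alone), with EXO1 at -2.02, FANCI at -1.93 and RAD51AP1 at -1.62. Camera gave adjusted p = 7.06e-30, 2.54e-25 and 3.68e-11 for the 3 lists, and adjusted p = 0.095, 0.095 and 0.11 with an estimated correlation. Metabolic genes fell too. Of 19 hypoxia and glycolysis genes, 11 fell and 2 rose (15 and 2 adjusted over the list alone), among them ALDOC (-1.65), ANKRD37 (-1.60), BNIP3 (-1.44) and LDHA (-0.92). Of 19 cholesterol and fatty acid synthesis genes, 10 fell and 1 rose (15 and 1 adjusted over the list alone), among them STARD4 (-1.56), MSMO1 (-1.44), FDPS (-1.362) and HMGCS1 (-1.12). These lists had adjusted p = 3.12e-07 and 3.22e-07, and adjusted p = 0.193 and 0.133 with an estimated correlation.

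Inflammatory and p53 target genes rose in SK-Mel5. Of 19 inflammatory and NF-kB genes, 11 rose and none fell (12 adjusted over the list alone), among them CXCL1 (1.89), LIF (1.45) and NFKBIA (0.84). Of 18 p53 target, CDK inhibitor and senescence genes, 11 rose and 1 fell (12 and 1 adjusted over the list alone), among them TP53I3 (1.51), the death receptor genes TNFRSF10B (1.10) and FAS (0.86), and MDM2 (0.68). Of 22 TGF-beta target and matrix genes, 7 rose and 1 fell (8 and 1 adjusted over the list alone), with SKIL at 1.361, ITGA5 at 1.04 and TGFB2 at -2.05. Camera gave adjusted p = 9.02e-07, 2.66e-05 and 0.0023, and adjusted p = 0.133, 0.095 and 0.11 with an estimated correlation. Other published MITF targets fell in 7 of 20 and rose in 2 (8 and 2 adjusted over the list alone), with PPARGC1A at -1.84, BEST1 at -1.82, GMPR at -1.66 and BCL2A1 at -1.48 (adjusted p = 0.00484; adjusted p = 0.193 with an estimated correlation). The pigment list did not pass (adjusted p = 0.0944): of 21 genes 7 fell and 2 rose (9 and 4 adjusted over the list alone), with TRPM1 at -1.95, MLANA at -1.47, GPR143 at -0.79 and TYR at 0.64.

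The remaining SK-Mel5 lists that passed lay nearer the threshold. Immediate early genes rose in 6 of 16 (6 adjusted over the list alone), with IER2 at 1.41, JUN at 1.34 and KLF2 at 1.04 (adjusted p = 0.0114; adjusted p = 0.193 with an estimated correlation). ERK output genes rose in 6 of 20 and fell in 4 (9 and 5 adjusted over the list alone), with CXCL8 at 1.57, SPRED1 at 1.01 and SPRY2 at 0.76 (adjusted p = 0.0457; adjusted p = 0.193 with an estimated correlation). Dedifferentiated melanoma markers rose in 3 of 18 (3 adjusted over the list alone), among them FOSL1 (0.78), with adjusted p = 0.0497, and adjusted p = 0.511 with an estimated correlation. Respiratory chain genes fell in 3 of 17 (3 adjusted over the list alone), among them NDUFA9 (-1.18) and UQCRC1 (-0.72), with adjusted p = 0.0271, and adjusted p = 0.267 with an estimated correlation. Histone genes fell in 4 of 12 and rose in 3 (7 and 3 adjusted over the list alone), with H1-5 at -1.94, H1-2 at -1.06 and H2BC5 at 1.04 (adjusted p = 0.0434; adjusted p = 0.22 with an estimated correlation). Without SK-Mel5 shp300 replicate 1 the adjusted p was 0.0797 for the ERK list, 0.171 for the dedifferentiated list (median 0.089, against 0.243 with all arrays) and 0.0797 for the respiratory list. Without SK-Mel5 scrambled replicate 1 it was 0.0734 for the dedifferentiated list, and without SK-Mel5 scrambled replicate 2 it was 0.0739 for the ERK list (median 0.189, against 0.287). Without SK-Mel5 shp300 replicate 2 it was 0.0625 for the ERK list and 0.101 for the histones (median -0.336, against -0.507). Leaving out dim features ended all 5 calls (adjusted p from 0.0595 for immediate early genes to 0.605 for histones; medians then 0.195, 0.287, 0.272, -0.221 and -0.208 for the immediate early, ERK, dedifferentiated, respiratory and histone lists, against 0.195, 0.287, 0.243, -0.221 and -0.507), and centring each array ended those of the ERK (0.0518) and dedifferentiated lists (0.0554). After quantile normalization or cyclic loess the dedifferentiated list had adjusted p = 0.0563 and 0.0786, and with the replicate number as a block 0.0568. The 12 acetyltransferase genes did not pass as a list (adjusted p = 0.259), with HAT1 at -1.71 and KAT2B at 0.90. The other lists that did not pass had adjusted p = 0.179 (stress response), 0.274 (leukocyte), 0.313 (antigen presentation), 0.659 (keratinocyte), 0.723 (fibroblast), 0.738 (endothelial), 0.739 (interferon), 0.762 (MYC targets), 0.795 (apoptosis), 0.808 (lysosome) and 0.82 (HEK293T). The stress response list passed without SK-Mel5 scrambled replicate 2 (adjusted p = 0.00914).

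The additive model over both lines estimated 1 change of the 4 arrays labelled shp300 against the 4 scrambled arrays. This change averages the lines, so a call need not hold in each of them. The MITF change, for example, was -1.71 in WM983B and -0.25 in SK-Mel5. SCG3 (3.10, SE 0.089) and SCG2 (2.90) rose, with the cytokine genes IL1B (2.74, SE 0.574), CXCL8 (2.62) and LIF (2.46), and MIR100HG (2.31), LIPH (2.22), UNC13A (2.06), EGR1 (2.00) and AGMO (1.98). The largest falls were in TRPM1 (-2.90), SLC19A2 (-2.72), ATP6V0D2 (-2.66), PRKCH (-2.63), the hyaluronan synthase gene HAS2 (-2.61), DEPDC1B (-2.53), G3BP2 (-2.52), MAP2K6 (-2.50), MLANA (-2.44) and the cyclophilin A gene PPIA (-2.38). As the rule for these 20 genes required, the arrays of the 2 groups did not overlap within either line. The rises of SCG3 (scrambled percentiles 20.4 in WM983B and 18 in SK-Mel5), IL1B (23.1 and 37.4), AGMO (30.5 and 42.8), LIPH (32.3 and 38), UNC13A (44.2 and 45.4) and SCG2 (45.2 and 39.7) started below the median feature in both lines, and the falls of PRKCH (shp300 percentiles 41.7 and 48.4) and MAP2K6 (48.5 and 44.3) ended below it, so their sizes are uncertain. FOXM1 fell by 1.94 (SE 0.091, adjusted p = 1.28e-05) and CREBBP rose by 0.81 (SE 0.109, adjusted p = 0.00129). MITF fell by 0.98 (SE 0.265, adjusted p = 0.0342), and the call was lost without WM983B scrambled replicate 1 (-0.82, adjusted p = 0.102) or 2 (-0.85, 0.104) and without WM983B shp300 replicate 1 (-0.92, 0.0975) or 2 (-0.76, 0.0834). The EP300 change was -0.54 (SE 0.194, adjusted p = 0.097), and it passed without WM983B shp300 replicate 2 (-0.70, adjusted p = 0.038) and as the mean of the 2 lines in the 4-group model (adjusted p = 0.00786). limma called 3991 features, 1815 higher and 2176 lower, of which 787 changed at least 2-fold. The count was 6143 as the mean of the 2 lines in the 4-group model and 2560 with the replicate number as a block. With that block the MITF call was lost too (-0.98, limma adjusted p = 0.0948).

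Of the 27 lists tested over both lines, 16 passed, 6 higher and 10 lower, and 3 of them also passed with an estimated correlation. These 3 were S phase genes (26 of 26 lower, 26 adjusted over the list alone, with MCM4 at -1.74 and RFC4 at -1.78), p53 targets (10 of 18 higher and 1 lower, 12 and 1 adjusted over the list alone, with TP53I3 at 1.10, TNFRSF10B at 1.04 and FAS at 0.84) and inflammatory genes (9 of 19 higher, 15 adjusted over the list alone, with ICAM1 at 0.82, NFKB2 at 0.73 and NFKBIA at 0.73). Their adjusted p was 1.09e-29, 2.42e-05 and 1.23e-06, and adjusted p = 0.0419 for each with an estimated correlation. G2/M genes fell in 25 of 26 (25 adjusted over the list alone), with BIRC5 at -1.71 and AURKB at -1.61 (adjusted p = 1.48e-29; adjusted p = 0.0621 with an estimated correlation); FOXM1 in this list was chosen on these arrays, so its direction is not independent evidence. DNA repair genes fell in 16 of 18 (adjusted p = 4.8e-15; adjusted p = 0.0743 with an estimated correlation) and TGF-beta genes rose in 7 of 22 (adjusted p = 0.000123; adjusted p = 0.0593 with an estimated correlation). The pigment and MYC target lists passed here but not in SK-Mel5 alone (camera adjusted p = 0.0944 and 0.762). Likewise the cholesterol and hypoxia lists passed here but not in WM983B alone (0.758 for each). With these, the other 10 lists that passed had adjusted p from 5.74e-06 to 0.00888, and adjusted p from 0.0967 to 0.48 with an estimated correlation. Of these, the cholesterol list was lost without SK-Mel5 scrambled replicate 2 (adjusted p = 0.056), and without dim features it (0.0665, median -0.206 as before) and the histone list (0.298, median -0.574 against -0.852) were lost. Among the lists that did not pass, the interferon list (adjusted p = 0.0925) passed without SK-Mel5 scrambled replicate 1 (0.0446) or 2 (0.0197) or SK-Mel5 shp300 replicate 1 (0.046) or 2 (0.0274). The HEK293T list (0.113) passed without SK-Mel5 scrambled replicate 1 (0.0476) or SK-Mel5 shp300 replicate 1 (0.046). Leukocyte markers did not pass (adjusted p = 0.397), though CD68, a lysosomal protein gene, fell by 1.60.

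**Figure D2:**
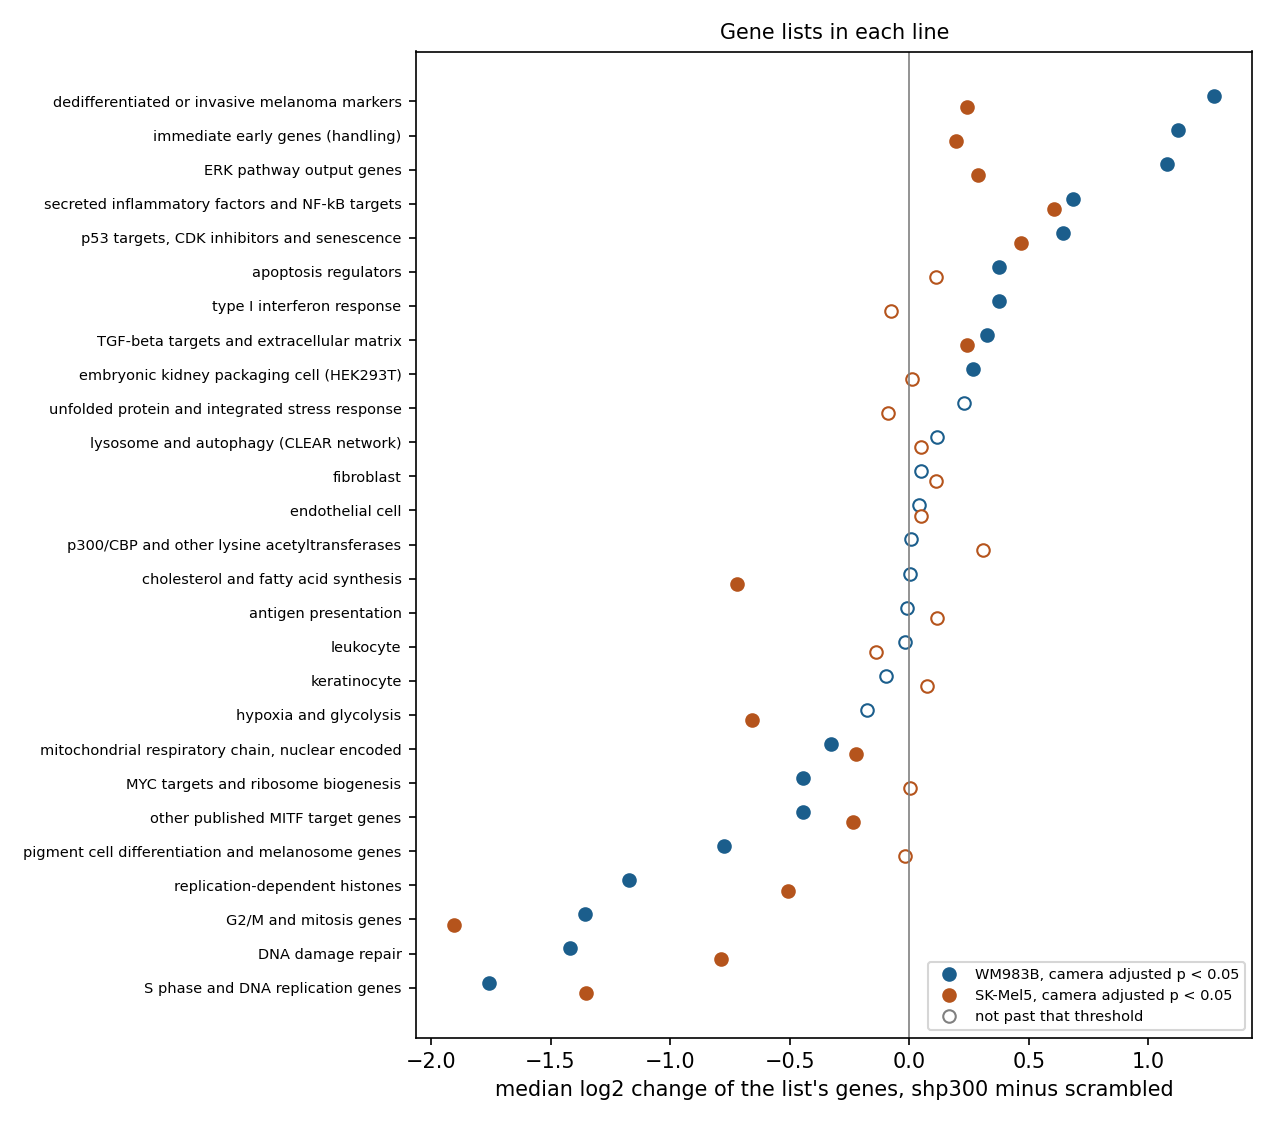
Median log2 change (shp300 minus scrambled, horizontal axis) of the genes of each of the 27 lists in WM983B and SK-Mel5, filled where the camera adjusted p with the preset correlation passed. The S phase list lies at -1.76 and -1.35 and the G2/M list at -1.358 and -1.90, while dedifferentiated markers lie at 1.28 in WM983B and 0.24 in SK-Mel5.

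Whether the same features moved in both lines was asked by comparing the 2 sets of changes, which share no arrays. Across the 23786 features the changes correlated at Pearson r = 0.452 and Spearman rho = 0.335; features are not independent replicates, so no p is given. Of the features called in both lines, 721 were higher in both (196.6 expected if calls were independent) and 1169 were lower in both (242.4 expected). Opposite calls numbered 105 for higher in WM983B and lower in SK-Mel5 (228.5 expected), and 101 for the reverse (208.6 expected). Both sets of calls used the same estimate of spread per feature, so they were not independent even where effects were unrelated. The expected numbers are therefore only a reference. A shared spread would raise calls in the same and in opposite directions alike, whereas opposite calls lay below these numbers.

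**Figure D3:**
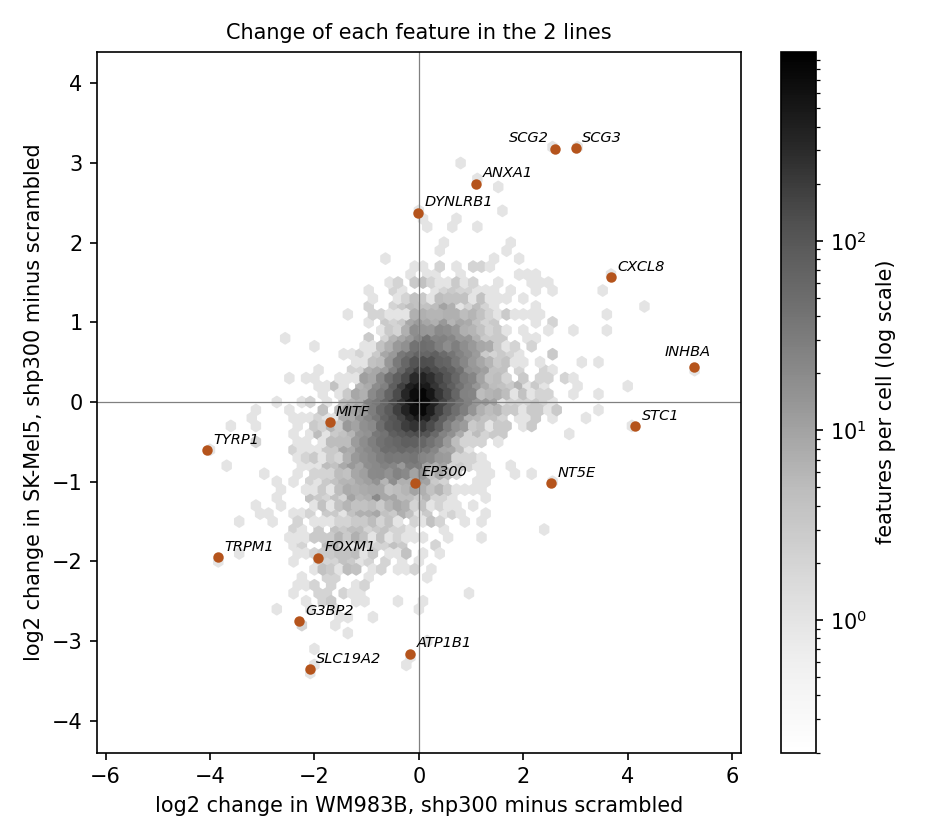
Log2 change of each feature in WM983B (horizontal axis) against SK-Mel5 (vertical axis), shp300 minus scrambled, as a density of the 23786 features with named genes marked. SCG3 and SCG2 lie high in both lines and FOXM1 and G3BP2 low in both, whereas INHBA (5.27 in WM983B, 0.45 in SK-Mel5) and ATP1B1 (-3.16 in SK-Mel5, -0.16 in WM983B) lie near an axis.

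The interaction test asked which effects differed between the lines, as the WM983B change minus the SK-Mel5 change. The mapping of probes to genes is not given for either line. Different probes behind a feature in each line were therefore not excluded, here or in the comparison of changes above. The largest positive differences were in INHBA, by 4.83 (SE 0.357), STC1 by 4.45, CDKN2B by 3.56, NT5E by 3.55 and TFPI2 by 3.42. NT5E, the gene of the surface enzyme CD73, rose by 2.54 in WM983B and fell by 1.02 in SK-Mel5. The largest differences the other way were in TYRP1 (-3.45), LINC00589 (-3.36), TUBBP5 (-3.34), GAPDHS (-2.999) and RPH3A (-2.94). TUBBP5 (adjusted p = 0.0115) lost its call without WM983B scrambled replicate 2 (0.0525). In SK-Mel5 several of these genes were dim in both groups and not shown to be above background, with percentiles (scrambled, shp300) of 19.2 and 32.3 for INHBA, 19 and 15.1 for CDKN2B, 29.8 and 31.8 for TFPI2, 19.9 and 39.8 for TUBBP5, 33.1 and 30.5 for GAPDHS, 18.6 and 12.2 for RPH3A and 49.2 and 45.6 for LINC00589. MITF fell more in WM983B, by -1.46 (SE 0.202, adjusted p = 0.0057). For FOXM1 the difference was 0.03 (95% interval -0.36 to 0.41, adjusted p = 0.949), and for CREBBP it was -0.23 (adjusted p = 0.547). The EP300 difference was 0.95 (SE 0.219, adjusted p = 0.0357). It was lost without WM983B scrambled replicate 1 (adjusted p = 0.119) or 2 (0.0953), WM983B shp300 replicate 2 (0.0963), SK-Mel5 scrambled replicate 1 (0.112), or SK-Mel5 shp300 replicate 1 (0.0839) or 2 (0.0672). The EP300 difference was also lost with the replicate number as a block (limma adjusted p = 0.062). limma called 2250 features, 1189 with a positive and 1061 with a negative difference. The count was 992 and 885 without WM983B scrambled replicates 1 and 2, 1404 and 1222 without WM983B shp300 replicates 1 and 2, 1035 and 1158 without SK-Mel5 scrambled replicates 1 and 2, 1410 without SK-Mel5 shp300 replicate 2, and 1351 with the replicate number as a block.

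Among gene lists, pigment genes had the lowest adjusted p for the difference with the preset correlation. Of 21, 9 had a negative difference and none a positive one (14 and 0 adjusted over the list alone; median -0.54), led by TYRP1, OCA2 (-2.80), MLANA (-1.94) and TRPM1 (-1.90), with adjusted p = 4.45e-09, and adjusted p = 0.197 with an estimated correlation. Dedifferentiated markers were positive in 10 of 18 (11 adjusted over the list alone; median 0.96), with CCN2 at 2.76, CCN1 at 2.65 and NGFR at 2.50 (adjusted p = 1.49e-06; adjusted p = 0.197 with an estimated correlation). ERK output genes were positive in 9 of 20 (11 adjusted over the list alone), with DUSP5 at 1.93, CCND1 at 1.66 and DUSP6 at 1.43 (adjusted p = 5.57e-06; adjusted p = 0.15 with an estimated correlation). Mitotic genes fell further in SK-Mel5: 10 of 26 G2/M genes had a positive difference (13 adjusted over the list alone), among them ASPM (1.27), BUB1 (1.02) and TOP2A (0.97), with adjusted p = 8.38e-06, and adjusted p = 0.241 with an estimated correlation. S phase genes fell further in WM983B, with 9 of 26 negative and 1 positive (10 and 1 adjusted over the list alone), among them CCNE1 (-1.20), GINS2 (-1.05) and TYMS (-0.97), with adjusted p = 9.88e-05, and adjusted p = 0.241 with an estimated correlation. The BUB1 call (adjusted p = 0.017) was lost without WM983B scrambled replicate 1 (0.0646) or 2 (0.0691), WM983B shp300 replicate 2 (0.0559) or SK-Mel5 scrambled replicate 2 (0.0611).

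Metabolic and stress genes also differed between the lines. Cholesterol genes were positive in 8 of 19 and negative in 1 (9 and 1 adjusted over the list alone), with HMGCS1 at 2.20, MSMO1 at 2.09 and INSIG1 at 1.53. Hypoxia genes were positive in 7 of 19 (10 adjusted over the list alone), with NDRG1 at 1.92, VEGFA at 1.64 and SLC2A3 at 1.51. Stress response genes were positive in 8 of 21 and negative in 1 (10 and 1 adjusted over the list alone), with CHAC1 at 2.64, DNAJB9 at 1.45 and DDIT3 at 1.15. These 3 lists had adjusted p = 8.38e-06, 1.48e-05 and 8.74e-05, and adjusted p = 0.197, 0.241 and 0.241 with an estimated correlation. The DDIT3 call (adjusted p = 0.0122) was lost without WM983B scrambled replicate 2 (0.0591) or SK-Mel5 scrambled replicate 1 (0.0516). Immediate early genes were positive in 7 of 16 and negative in 1 (9 and 2 adjusted over the list alone), with EGR3 at 2.65 and FOSB at 1.91 (adjusted p = 0.000146; adjusted p = 0.197 with an estimated correlation). MYC targets were negative in 5 of 20 and positive in 1 (6 and 1 adjusted over the list alone), with BOP1 at -1.62, FBL at -0.77 and ODC1 at 0.95 (adjusted p = 0.000293; adjusted p = 0.197 with an estimated correlation). Interferon genes were positive in 5 of 23 (9 positive and 1 negative adjusted over the list alone), with IFI27 at 1.43, IRF9 at 1.301 and OAS2 at 1.13 (adjusted p = 0.000293; adjusted p = 0.178 with an estimated correlation). DNA repair genes were negative in 5 of 18 (5 adjusted over the list alone), with LIG1 at -1.18 and RAD54L at -1.15 (adjusted p = 0.000804; adjusted p = 0.241 with an estimated correlation). The call was lost for FBL (adjusted p = 0.0217) without WM983B scrambled replicate 2 (0.0868), WM983B shp300 replicate 1 (0.0606) or 2 (0.0613), SK-Mel5 scrambled replicate 1 (0.0777) or 2 (0.0589) or SK-Mel5 shp300 replicate 2 (0.0567), and with the replicate number as a block (0.0579). It was lost for ODC1 (adjusted p = 0.021) without WM983B scrambled replicate 1 (0.0817) or 2 (0.0605), WM983B shp300 replicate 2 (0.0715), SK-Mel5 scrambled replicate 1 (0.0719) or SK-Mel5 shp300 replicate 1 (0.0548), and with the replicate number as a block (0.0543). The same held for IFI27 (adjusted p = 0.03) without WM983B scrambled replicate 1 (0.0951) or 2 (0.103), SK-Mel5 scrambled replicate 1 (0.0915) or 2 (0.0839) or SK-Mel5 shp300 replicate 1 (0.0747) or 2 (0.0618) and after quantile normalization of all arrays (1.105, 0.0572), and for IRF9 (adjusted p = 0.0181) without WM983B shp300 replicate 1 (0.0601) or 2 (0.057) or SK-Mel5 scrambled replicate 2 (0.0657). LIG1 lost its call (adjusted p = 0.0204) without WM983B scrambled replicate 1 (0.0746) or 2 (0.0783), SK-Mel5 scrambled replicate 1 (0.06) or 2 (0.072) or SK-Mel5 shp300 replicate 2 (0.0603).

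The last 4 lists that passed for the difference did so less firmly. Histones were negative in 3 of 12 and positive in 1 (5 and 1 adjusted over the list alone), with H4C1 at -1.72 and H2BC5 at 1.46 (adjusted p = 0.00988; adjusted p = 0.203 with an estimated correlation; adjusted p = 0.0581 after quantile normalization). Antigen presentation genes were negative in 3 of 18 (3 adjusted over the list alone), with HLA-DRA at -1.18 and TAP2 at -1.08 (adjusted p = 0.0214; adjusted p = 0.241 with an estimated correlation). Of 8 HEK293T markers, 1 was positive (1 adjusted over the list alone), CDH2 at 1.03 (adjusted p = 0.0411; adjusted p = 0.234 with an estimated correlation). Apoptosis regulators were positive in 5 of 19 and negative in 2 (6 and 2 adjusted over the list alone), with PMAIP1 at 2.45, CASP9 at 1.70 and BAX at -1.18 (adjusted p = 0.044; adjusted p = 0.241 with an estimated correlation). The antigen call was lost without SK-Mel5 scrambled replicate 1 (adjusted p = 0.0823) or SK-Mel5 shp300 replicate 2 (0.0513). The HEK293T call was lost without WM983B shp300 replicate 1 (0.0874), SK-Mel5 scrambled replicate 1 (0.0823) or SK-Mel5 shp300 replicate 1 (0.113). The apoptosis call was lost without WM983B scrambled replicate 2 (0.0519), WM983B shp300 replicate 2 (0.119), SK-Mel5 scrambled replicate 1 (0.0943) or 2 (0.0507) or SK-Mel5 shp300 replicate 2 (0.0974), and with the replicate number as a block (0.0533). Leaving out dim features ended these 4 calls (0.195, 0.076, 0.076 and 0.0928) and that of the interferon list (0.0993), with medians of -0.344, -0.142, 0.776, 0.246 and 0.253, against -0.443, -0.127, 0.361, 0.262 and 0.577 with all features. The inflammatory (adjusted p = 0.266) and p53 lists (0.83) did not pass for the difference.

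The last comparison set scrambled WM983B against scrambled SK-Mel5, since the series title links MITF expression to vulnerability to p300 inhibition. On the deposited scale the median feature was 0.93 higher in WM983B, so changes are also given relative to this shift. MITF was 1.51 higher in WM983B (SE 0.143, adjusted p = 2.55e-05), or 0.57 relative to the shift, and stood at percentile 94.3 of the WM983B features and 92.0 of the SK-Mel5 features. After centring each array the MITF difference was 0.24 (adjusted p = 0.172), after quantile normalization 0.40 (0.056), and after cyclic loess 0.42 (0.0412). FOXM1 was 1.56 higher, or 0.63 relative to the shift, and 0.29 after centring (adjusted p = 0.0688). EP300 was 0.11 higher as deposited (adjusted p = 0.506) but -1.15, -1.03 and -1.01 after centring, quantile normalization and loess. CREBBP turned in the same way, from 0.41 to -0.85, -0.74 and -0.69, and its deposited call was lost without WM983B scrambled replicate 1 (adjusted p = 0.0866) or 2 (0.0655) or SK-Mel5 scrambled replicate 2 (0.109).

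The 10 largest positive differences as deposited were in HSPA1A (9.98), SLC43A3 (9.32), CAPG (8.89), PYCARD (8.43), H3C11 (8.38), CD74 (8.07), TMSB4X (8.01), ENPP2 (7.86), HEXA (7.79) and FXYD3 (7.43). The 10 largest negative differences were in MERTK (-6.21), GAGE13 (-6.12), CT45A5 (-6.10), PRAME (-5.67), PKD1L1-AS1 (-5.64), PAPSS2 (-5.43), IL13RA2 (-5.31), MGP (-5.17), PEG10 (-5.16) and EDA2R (-5.11). The near-identical genes HSPA1A and HSPA1B stood at 10.73 and 9.46 in scrambled WM983B but at 0.75 and 7.43 in scrambled SK-Mel5. In the line where they were lower, the 20 genes stood at percentiles from 0.2 (HSPA1A) to 53.3 (H3C11), signals not all shown to be above background. The lines are not on a common scale and the mapping of probes to genes is not given for either, so the sizes of these differences are uncertain, and different mappings of the 2 lines were not excluded. limma called 19582 features, 18719 higher and 863 lower in WM983B; after centring each array it called 15654, 4689 higher and 10965 lower, and after quantile normalization and loess 11512 and 11596.

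Relative to all other genes, 6 lists passed between the scrambled lines. S phase, G2/M, DNA repair, interferon and antigen presentation genes were higher in WM983B (median differences relative to the shift 1.09, 1.08, 1.02, 0.98 and 0.55), with BST2 (7.18), HLA-DRA (6.27), IFI44 (5.30) and OAS1 (4.76) among them. Their adjusted p was 0.000273, 0.000216, 0.00378, 0.00879 and 0.0254, and adjusted p = 0.554, 0.569, 0.554, 0.342 and 0.554 with an estimated correlation. The p53 and CDK inhibitor list was lower relative to other genes (median -0.09, or -1.02 relative to the shift, with a mean of 0.39), though CDKN2A (4.47) and PHLDA3 (3.08) were higher and CDKN1A was -1.29 (adjusted p = 4.2e-07; adjusted p = 0.0975 with an estimated correlation). The antigen list was lost after quantile normalization (adjusted p = 0.0584), after cyclic loess (0.0563), with the replicate number as a block (0.0593) and without dim features (0.173), and without dim features so were the interferon (0.0847) and repair lists (0.077). The medians of these 3 lists without dim features were 1.512, 2.487 and 1.956, against 1.479, 1.916 and 1.956 with all features. Other lists passed only on another scale: histones after centring, quantile normalization and loess (adjusted p = 8.22e-05, 0.00258 and 0.003, against 0.142 as deposited), dedifferentiated markers likewise (0.00289, 0.0368 and 0.048, against 0.738), all of these higher in WM983B. The inflammatory list passed after centring (higher, 0.032, against 0.992) and the cholesterol list after loess (lower, 0.048, against 0.259). The pigment list (adjusted p = 0.579) and the other MITF targets (0.706) did not pass.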

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

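The tests that weigh an explanation below were chosen for that use after the result was seen, though the joint quantile normalization, the left-out arrays and the G2/M list test among them were planned, as was the count of other splits of the arrays; its restriction to balanced splits was not planned. The results below were singled out because the effect of the shRNA differed between the lines by limma's interaction test (adjusted p under 0.05). Each value is the WM983B change minus the SK-Mel5 change on the log2 scale. WM983B changes are those of arrays labelled shp300, on which EP300 RNA was not measurably lower.

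The first pattern is that EP300 RNA fell in SK-Mel5 but was not measurably lower on the WM983B arrays labelled shp300 (difference 0.95, adjusted p = 0.0357). With the replicate number as a block this difference was not called (limma adjusted p = 0.062). The interaction call was lost without WM983B scrambled replicate 1 (0.119) or 2 (0.0953), WM983B shp300 replicate 2 (0.0963), SK-Mel5 scrambled replicate 1 (0.112) or SK-Mel5 shp300 replicate 1 (0.0839) or 2 (0.0672). An exchange of single arrays between the WM983B groups is argued against, because every WM983B array correlated better with its group mate than with the other group, by at least 0.0174 in r, and an exchange of the whole groups is argued against by the positive correlation of the 2 lines' changes (r = 0.452, at least 0.41 with any array left out). A feature unable to show a fall in WM983B stays open: the feature of the same number fell in SK-Mel5 (-1.01), but the probes behind it are not given for either line. A return of EP300 RNA to its control level by harvest, or a loss of p300 without a loss of RNA, may account for it and stays open: the 95% limit has a lower bound of -0.425, and p300 protein was not analysed here. Both readings take p300 as lowered in WM983B, which these data do not show. The WM983B changes can therefore not be tied to a loss of p300. In SK-Mel5 the changes came with lower EP300 RNA. Whether the shRNA also matches other transcripts was not tested for either line. The SK-Mel5 changes are thus not shown to come from a loss of p300 alone.

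The second pattern is that MITF fell more in WM983B than in SK-Mel5 (difference -1.46, adjusted p = 0.0057). The separate normalization of the lines is argued against as its whole cause, since the difference was -1.478 after quantile normalization of all 8 arrays. A narrower range of the SK-Mel5 arrays is argued against only as the whole cause, since G2/M genes fell further in SK-Mel5 (median difference 0.488; adjusted p = 0.241 with an estimated correlation); a part stays open, as S phase (-0.484), repair (-0.377) and histone genes (-0.443) fell less there and the SD of all changes was 0.44 against 0.512 in WM983B. A property of the lines, such as their starting MITF level, may contribute and stays open: scrambled MITF was 0.397 higher in WM983B after joint quantile normalization (adjusted p = 0.056), and 1 line of each kind cannot separate it from any other trait of the lines. The probes behind the MITF feature are not given for either line, so different mappings were not excluded here either.

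Other splits of the 8 arrays into 4 and 4 were fitted with the additive model. There are 35 such splits, of which 34 could be fitted, because 1 equals the lines themselves. Only 18 of them hold 2 arrays of each line in each group as the real split does, and the rest mix the shRNA with the line. These 18 are too few for a share under 0.05. The real split called 3991 genes, and the highest other, among the 18 as among the 34, called 8 (1 split with as many, the real one). It called 16 gene lists, and the highest other called 18; 4 of the 18 splits, and 7 of the 34, called at least as many. Of the 18, 8 splits keep the real shRNA contrast of 1 line whole and called 7 to 18 lists, so they are no measure of chance alone. The 8 that mix the shRNA in both lines called 0 lists and 0 genes. In those 8 the shRNA effect enters the spread within the groups, which keeps calls low whatever the cause. The splits thus give no measure of chance for either count.

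Among the genes with the largest changes the difference was positive for INHBA (4.83), IL1B (3.13), STC1 (4.45), CXCL8 (2.12), LIPH (2.68), MIR100HG (2.47), TFPI2 (3.42), LIF (2.02), CDKN2B (3.56) and PMEPA1 (2.94). It was also positive for the surface enzyme gene NT5E (3.56) and SLC19A2 (1.27), the last of which fell in both lines. Dedifferentiation and ERK genes gave CCN2 (2.76), CCN1 (2.65), NGFR (2.50), DUSP5 (1.93), DUSP6 (1.43), SPRY2 (0.80), CCND1 (1.66), EGR3 (2.65) and FOSB (1.91). Inflammatory and matrix genes gave CCL2 (2.77), PTGS2 (1.77), ITGA5 (1.28), COL4A1 (1.06), CDH2 (1.03) and TGFB2 (1.99), and the inflammatory gene CXCL1 gave -1.45.

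Pigment genes differed the other way, as TYRP1 (-3.45), TRPM1 (-1.90), MLANA (-1.94) and OCA2 (-2.80) did. Further falls of WM983B gave CST1 (-2.86), LINC00589 (-3.36), ATP6V0D2 (-1.56), CDCA7 (-1.88), RPH3A (-2.94), CRYAB (-2.55), PLA1A (-2.81), GAPDHS (-2.999) and TUBBP5 (-3.34). Genes with larger rises in SK-Mel5 gave CHGB (-2.25), ANXA1 (-1.64), UNC13A (-1.22), DYNLRB1 (-2.40), ACTA2 (-1.52), MMP1 (-2.21), MAPRE3 (-2.09), CHGA (-1.99) and GDAP1 (-1.356). Genes with larger falls in SK-Mel5 gave PKD1L1-AS1 (3.10), PRKCH (1.23), ATP1B1 (2.99), MAP2K6 (1.13), DEPDC1 (1.60) and LOC100505912 (3.12). The WM983B signals of genes with larger rises or falls in SK-Mel5 were not compared with background. Where such a feature was dim in WM983B, the size of the difference is uncertain. Scrambled CHGA (2.19), CHGB (3.01) and UNC13A (3.76) lay below the WM983B array median of 4.27, while DYNLRB1 (11.28) and GDAP1 (7.36) lay above it. PKD1L1-AS1 was among the features most reduced in scrambled WM983B relative to scrambled SK-Mel5, which left less room for a fall in WM983B. The call was lost for TUBBP5 (adjusted p = 0.0115) without WM983B scrambled replicate 2 (0.0525), for CHGB (adjusted p = 0.0221) without WM983B scrambled replicate 2 (0.0805), WM983B shp300 replicate 1 (0.0628) or 2 (0.0801), SK-Mel5 scrambled replicate 2 (0.059) or SK-Mel5 shp300 replicate 1 (0.0593), and for UNC13A (adjusted p = 0.0173) without WM983B scrambled replicate 1 (0.0706), WM983B shp300 replicate 1 (0.0538), SK-Mel5 scrambled replicate 2 (0.057) or SK-Mel5 shp300 replicate 2 (0.0509) and with the replicate number as a block (0.0514).

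Cell-division and repair genes gave GINS2 (-1.05), MCM5 (-0.73), MCM6 (-0.65), TYMS (-0.97), CCNE1 (-1.20), RAD54L (-1.15) and LIG1 (-1.18), the S phase gene CCNA2 (0.96) with the one positive difference of its list, and mitotic genes PLK1 (0.70), BUB1 (1.02), TOP2A (0.97) and ASPM (1.27). Histone and MYC target genes gave H4C1 (-1.72), H2BC5 (1.46), FBL (-0.77), CAD (-0.67), BOP1 (-1.62) and ODC1 (0.95). BUB1, LIG1, FBL and ODC1 were called unstably: the call was lost for BUB1 (adjusted p = 0.017) without WM983B scrambled replicate 1 (0.0646) or 2 (0.0691), WM983B shp300 replicate 2 (0.0559) or SK-Mel5 scrambled replicate 2 (0.0611). Likewise it was lost for LIG1 (adjusted p = 0.0204) without WM983B scrambled replicate 1 (0.0746) or 2 (0.0783), SK-Mel5 scrambled replicate 1 (0.06) or 2 (0.072) or SK-Mel5 shp300 replicate 2 (0.0603). For the MYC targets it was lost for FBL (adjusted p = 0.0217) without WM983B scrambled replicate 2 (0.0868), WM983B shp300 replicate 1 (0.0606) or 2 (0.0613), SK-Mel5 scrambled replicate 1 (0.0777) or 2 (0.0589) or SK-Mel5 shp300 replicate 2 (0.0567) and with the replicate number as a block (0.0579), and for ODC1 (adjusted p = 0.021) without WM983B scrambled replicate 1 (0.0817) or 2 (0.0605), WM983B shp300 replicate 2 (0.0715), SK-Mel5 scrambled replicate 1 (0.0719) or SK-Mel5 shp300 replicate 1 (0.0548) and with the replicate number as a block (0.0543).

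Metabolic and stress genes gave ANKRD37 (1.33), FDPS (0.73), MSMO1 (2.09), HMGCS1 (2.20), STARD4 (1.365), INSIG1 (1.53), VEGFA (1.64), NDRG1 (1.92) and SLC2A3 (1.51), and CHAC1 (2.64), DNAJB9 (1.45), DDIT3 (1.15) and SESN2 (0.91). Cell death and p53 target genes gave CASP9 (1.71), PMAIP1 (2.45), BAX (-1.18), MCL1 (0.88), BCL2A1 (1.15), TP53I3 (-0.82), MDM2 (-0.94) and RRM2B (-0.93). Interferon and antigen genes gave IFI27 (1.43), IRF9 (1.301), OAS2 (1.12), RSAD2 (1.01), TAP2 (-1.08) and HLA-DRA (-1.18). The remaining genes were KLF2 (-1.01), KAT2B (-0.95), MT1X (1.96), MT2A (1.25), SYP (1.64) and VGF (2.06). Calls were lost for DDIT3 (adjusted p = 0.0122) without WM983B scrambled replicate 2 (0.0591) or SK-Mel5 scrambled replicate 1 (0.0516), for IFI27 (adjusted p = 0.03) without WM983B scrambled replicate 1 (0.0951) or 2 (0.103), SK-Mel5 scrambled replicate 1 (0.0915) or 2 (0.0839) or SK-Mel5 shp300 replicate 1 (0.0747) or 2 (0.0618) and after quantile normalization (0.0572), and for IRF9 (adjusted p = 0.0181) without WM983B shp300 replicate 1 (0.0601) or 2 (0.057) or SK-Mel5 scrambled replicate 2 (0.0657).

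Of the 27 gene lists, 16 differed between the lines, by these medians. The median difference was -0.54 for pigment genes, 0.96 for dedifferentiated markers, 0.49 for G2/M genes, -0.48 for S phase genes and 0.58 for interferon genes. It was -0.13 for antigen presentation, 0.42 for cholesterol synthesis, 0.69 for the stress response, 0.50 for hypoxia and -0.36 for MYC targets. For ERK output it was 0.58, for apoptosis regulators 0.26, for DNA repair -0.38, for histones -0.44, for immediate early genes 0.60 and for HEK293T markers 0.36. With an estimated correlation camera called none of the 27 lists (0 called, lowest adjusted p = 0.15, 6 with an unadjusted p under 0.05), while fry called 21. The antigen, HEK293T and apoptosis calls each depended on single arrays: antigen was lost without SK-Mel5 scrambled replicate 1 (adjusted p = 0.0823) or SK-Mel5 shp300 replicate 2 (0.0513). HEK293T was lost without WM983B shp300 replicate 1 (0.0874), SK-Mel5 scrambled replicate 1 (0.0823) or SK-Mel5 shp300 replicate 1 (0.113). Apoptosis was lost without WM983B scrambled replicate 2 (0.0519), WM983B shp300 replicate 2 (0.119), SK-Mel5 scrambled replicate 1 (0.0943) or 2 (0.0507) or SK-Mel5 shp300 replicate 2 (0.0974).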

How the results depend on the processing

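The alternatives below were planned before the data were examined. Within each line, EP300, MITF and FOXM1 kept their direction and their side of the threshold under every alternative run, except that the EP300 change in WM983B, called nowhere, turned to 0.10 without WM983B shp300 replicate 1. Leaving out 1 array at a time, counts ran from 3146 to 5398 in WM983B, 2143 to 3648 in SK-Mel5 and 885 to 1784 for the difference between lines. MITF over both lines ran from -1.15 to -0.76, EP300 over both lines from -0.70 to -0.39, the EP300 difference from 0.78 to 1.12, and the correlation of the lines from 0.41 to 0.446. With the replicate number as a block, 4563 features were called in WM983B, 3161 in SK-Mel5, 2560 over both lines and 1351 for the difference. MITF over both lines (-0.98, limma adjusted p = 0.0948) and the EP300 difference (0.95, limma adjusted p = 0.062) were then not called. Deviations of arrays with the same number from their group means correlated at 0.00303 in WM983B and 0.0277 in SK-Mel5. No strong shared effect of the number was thus seen. The labels do not say whether such arrays were handled together, so a pairing was not excluded. Over both lines 2291 features changed at least 1.5-fold, the 4-group mean called 6143, and EP300 (-0.54) passed with the 4-group mean and at an adjusted p under 0.1, by the alternative's own construction. For the difference 3404 features had an adjusted p under 0.1, and from only the 4 SK-Mel5 arrays 2050 were called, with fewer arrays to estimate the spread. With an estimated correlation camera called 0 lists in WM983B, 0 in SK-Mel5, 3 over both lines, 0 for the difference and 0 between scrambled lines (13, 7, 9, 6 and 2 with an unadjusted p under 0.05). In place of camera, fry mixed called 26, 24, 25, 27 and 27. Leaving out dim features left 9 lists in SK-Mel5 and 3 between scrambled lines, 10717 features between scrambled lines and a correlation of 0.528, against 0.335 for Spearman. Between scrambled lines, where the separate normalization enters, quantile normalization called 11512 and loess 11596. After centring, quantile normalization and loess EP300 was -1.15, -1.03 and -1.01 and CREBBP -0.85, -0.74 and -0.69. MITF was 0.24 after centring and 0.40 after quantile normalization, and FOXM1 was 0.29 after centring. There fry, which tests against 0 and not against other genes, called 27 lists higher, turning 15: the medians were 0.97 for acetyltransferases, 1.07 for pigment, 1.16 for other MITF targets, -0.089 for p53, 0.58 for cholesterol, 0.90 for stress response, 1.48 for hypoxia and 1.00 for lysosome. They were 0.83 for MYC, 1.11 for ERK, 0.95 for TGF-beta, 1.03 for apoptosis, 0.65 for immediate early, 0.73 for keratinocyte and 0.68 for HEK293T. For the changes whose construction is not named here, the cause was not tested. Of the values of named genes that passed in neither fit, 24 changed sign, and sign changes of gene lists were not counted. Background values were not used here, so what signal near it limits was not measured; the WM983B calls of the histone, interferon, apoptosis and HEK293T lists ended without dim features, though the apoptosis and HEK293T medians did not shrink.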

Other observations

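The genes below were chosen after their values were seen, and so was the test of REST RNA in WM983B; the second REST target list and its test in SK-Mel5 were chosen after the main results but before that list's values were seen. On the WM983B arrays labelled shp300, of 12 measured features of the metallothionein genes MT1 and MT2, whose proteins bind zinc and copper, 3 rose and 0 fell, MT1E by 2.49, MT1X by 1.99 and MT2A by 0.53. In SK-Mel5 0 rose and 1 fell, MT2A by -0.72, and MT1X was 0.03 and MT1E 0.58 (adjusted p = 0.935 and 0.455). Scrambled MT1E stood there at 1.11, near the 5th percentile of the 2 arrays (1.06 and 1.03). It was not shown to be above background, so its change there and its difference between lines are uncertain. The difference between lines passed for MT1X (1.96, adjusted p = 0.00141) and MT2A (1.25, 0.00376), and not for MT1E (1.91, 0.0932). MT2A in WM983B lost its call without WM983B scrambled replicate 2 (adjusted p = 0.0673) or WM983B shp300 replicate 2 (0.0563). MT1E passed in SK-Mel5 without SK-Mel5 shp300 replicate 1 (0.00435), and its difference passed without SK-Mel5 shp300 replicate 1 (0.032) or 2 (0.00336), without dim features (0.0459) and with trend and robust eBayes (0.0403).

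Of some neuronal and secretory vesicle genes, picked because of their values and not tested as a set, several rose and others did not. In WM983B SCG3 rose by 3.01 (from percentile 20.4, not shown to be above background), SCG2 by 2.61, SYP by 2.50, VGF by 2.42, RUNDC3A by 2.155, UNC13A by 1.45 and CHRNB2 by 1.33, while CHGB was 0.74 (adjusted p = 0.157) and GDAP1 -0.048 (adjusted p = 0.849). In SK-Mel5, beside SCG3, SCG2 and CHGB, RUNDC3A rose by 1.60, CHGA by 1.50, GDAP1 by 1.31, CHRNB2 by 1.26 and SYP by 0.86, while VGF was 0.35 (adjusted p = 0.128). Scrambled SCG2 (3.83), UNC13A (3.76), CHRNB2 (3.55) and RUNDC3A (4.18) in WM983B also lay below the array median of 4.27. So did scrambled CHGB (3.01) and CHGA (2.19), so the sizes of their WM983B changes are uncertain. SYP (4.41), VGF (7.75) and GDAP1 (7.36) lay above it. In SK-Mel5, scrambled RUNDC3A (2.68) and CHRNB2 (2.36) lay below the median of 2.99. The sizes of these rises are uncertain. The SK-Mel5 call of CHRNB2 was lost without SK-Mel5 scrambled replicate 1 (0.0609), and that of SYP without SK-Mel5 scrambled replicate 2 (0.0722) or SK-Mel5 shp300 replicate 1 (0.0729); both were lost from the 4 SK-Mel5 arrays alone (0.065 and 0.0866). VGF in SK-Mel5 passed with trend and robust eBayes (0.0267), and the SCG3 difference between lines, not called otherwise, after quantile normalization (-0.707, adjusted p = 0.0337). In WM983B CHGA was -0.49 (adjusted p = 0.0816), called without SK-Mel5 scrambled replicate 1 (0.0244) or 2 (0.0244) and from the 4 WM983B arrays alone (0.0312).

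A candidate explanation is lower REST, the repressor of neuronal genes. REST RNA fell by 0.67 in SK-Mel5 (SE 0.150, adjusted p = 0.0196), a call lost without SK-Mel5 scrambled replicate 1 (0.118) or 2 (0.0536) or SK-Mel5 shp300 replicate 1 (0.064) or 2 (0.0802). A second list of 18 REST target genes, free of those seen, had a median change of 0.26 in SK-Mel5 (6 rose, 1 fell; limma camera, adjusted p = 0.0128), as lower REST would give, but not with an estimated correlation (adjusted p = 0.084). In WM983B, REST changed by 0.004 (95% interval -0.34 to 0.35). This argues against lower REST RNA as the cause of the rises there. REST protein was not analysed here, so a loss of REST without a loss of its RNA stays open. The second list of 18 genes had a median of 0.076 in WM983B (4 rose, 1 fell; limma camera, adjusted p = 0.0988). A first list of 22 REST targets, chosen after values were seen, passed in both lines: 7 rose and 0 fell in WM983B, where REST did not change measurably (median 0.192, limma camera adjusted p = 0.00564; adjusted p = 0.0804 with an estimated correlation), and 6 rose and 0 fell in SK-Mel5 (median 0.263, adjusted p = 0.000888; adjusted p = 0.0804 with an estimated correlation). These p-values were adjusted over 6 tests, of 2 REST lists in 3 comparisons, and this adjustment was chosen after the values were seen. Those of the first list are not independent evidence, since that list too was chosen after values were seen. Between the lines the second list had a median difference of -0.03 (0 positive, 1 negative, limma camera, adjusted p = 0.536). A larger rise in the line where REST fell was thus neither shown nor excluded, and lower REST stays open for SK-Mel5. The REST difference between lines did not pass (0.67, adjusted p = 0.0962), but it did without dim features (0.0401) and with trend and robust eBayes (0.0492).

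G3BP2 and PPIA fell in both lines, G3BP2 by -2.29 in WM983B and -2.75 in SK-Mel5, and PPIA by -2.16 and -2.60. The G3BP2 difference between lines passed only with trend and robust eBayes (0.466, adjusted p = 0.023). HAS2 fell by -2.66 and -2.56. Whether the shRNA matches any of these transcripts was not tested, since its sequence was not used here. DYNLRB1 rose in SK-Mel5 by 2.38 and was -0.02 in WM983B, a difference of -2.39 (limma adjusted p = 0.000362). Different probes behind its feature in each line were not excluded.

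Between the scrambled lines, 44 features with a symbol stood at least 5 log2 units above the median difference and 20 at least 5 below it. Among the former, HEXA stood at 9.17 in WM983B and 1.38 in SK-Mel5, and TMSB4X at 10.54 and 2.53. The lines are not on a common scale and the mapping of probes to genes is not given for either. Different mappings were not excluded as the source of such differences.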
